A study of Homo sapiens with 3 samples.

How the data were processed

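Polyadenylated RNA was sequenced from 3 libraries, with 1 library per group: MM.1S human multiple myeloma cells grown alone, MM.1S cells isolated after 24 h of co-culture with HS5 cells, and HS5 cells grown alone. HS5 is an immortalised human bone marrow stromal line. Per the labels' protocols, poly(A) RNA was fragmented in alkaline buffer, fragments of 50 to 100 bases were selected on gels, and the libraries were made by linker ligation, reverse transcription, circularisation and PCR. Reads were single-end and 50 bases long. The co-cultured MM.1S cells had been separated from HS5 with the detachment enzyme mix Accutase and magnetic beads against CD138, a plasma cell surface protein. The labels give the enrichment of both monocultures as none.

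Alignment used Bowtie 0.12.8 and the human build hg19, per the submitters' processing notes. The program that assigned reads to genes was not given in the sources used here. Raw read counts per transcript were deposited by the authors, per the file headers, with no normalization. The same table held RPKM values deposited by the authors, per the file headers, that is reads scaled to transcript length and to the library total. It had 7970 rows under UCSC transcript identifiers. Every RPKM value was above 1 in all 3 libraries, the lowest being 1.00244, so transcripts low in any library were not in the table used here. Genes specific to either cell type could be left out in this way: 3 of 31 listed stromal markers and 13 of 26 listed plasma cell identity genes were present. Of the rows, 18 had no gene symbol and 16 held a symbol turned into a date number. These 34 rows entered the counts of genes and could not be named. The symbols H3F3B and HLA-B stood on 2 rows each, and HLA-B in particular shares sequence with its relatives, so its values are uncertain. No coordinates are given, since no reference of the build hg19 was used here.

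The table does not state library totals. They were recovered as the whole number at which reads, RPKM and a whole transcript length agree, and came to 10343703 reads for MM.1S alone, 11763251 for co-cultured MM.1S and 5777398 for HS5. With these totals the lengths lay within 0.05 bases of a whole number for at least 99.1% of rows. Adding 1 base gave a multiple of 3 in 99.99% of rows, so the lengths used by the authors were coding lengths, with a median of 1403 bases. The reads in the table made up 30.1%, 28.3% and 16.3% of these totals. What the remaining reads were is not known from the table, nor whether they differed in kind between libraries, so the scaling to these totals is uncertain.

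Read counts plus a pseudocount of 0.5 were divided by the recovered library total to give CPM, and log2 ratios were taken between libraries. Genes needed 50 counts in at least 1 library of a comparison, which left 7200 rows for co-cultured against monoculture MM.1S and 7081 for HS5 against MM.1S. Genes at least 2-fold apart were counted. With 1 library per group there was no replicate check, and no p-value is given. Each ratio has an exact 95% Clopper-Pearson interval, conditional on the sum of both counts. Intervals of a list's median are order-statistic intervals over its genes. The PCR reads carried no molecular identifiers, so intervals cover counting error only, and every comparison describes these libraries and not the conditions.

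HS5 RNA in the co-culture library was to be estimated as the median over stromal markers of the co-culture CPM minus the monoculture CPM, divided by the HS5 CPM minus the monoculture CPM. Markers needed 50 counts in HS5 and a monoculture level of at most 1% of HS5. Only FN1 met this in the filtered table, and its estimate was below 0, so the subtraction fixed before the data were examined took off 0 and left every value as it was. FN1, MME and S100A6, the genes above 100 CPM in HS5 that met the 1% limit, gave upper limits in its place.

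The 25 gene lists, the sizes, the alternatives and the rule for named genes were fixed before the data were examined. The rule took genes by the bound of the counting interval nearest to 0: the 8 highest in co-culture, the 15 furthest above both monocultures, the 15 lowest in co-culture, and the 10 highest and 10 lowest in HS5 against MM.1S. It added up to 4 members of each list with the largest ratios and any member of the STAT3, JAK-STAT, stromal and plasma cell lists. Some genes that the rule takes are not reported here. A further 228 listed symbols were not in the table used here. Each list with 3 or more measured genes was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched over 20 bins of mean expression. A percentile is a description of these libraries and not a test.

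Alternatives were TMM factors from edgeR 4.0.16, median-of-ratios size factors from DESeq2 1.42.0 (R 4.3.3), the authors' RPKM with a pseudocount of 0.1, minimums of 20 and 200 counts or none, a pseudocount of 5, the whole interval beyond 2-fold, other HS5 shares, and library totals without the 20 most abundant genes. Added after seeing the data were the sums of the table as totals, TMM over the MM.1S libraries alone, centring on the median of all genes, HS5 shares at the FN1 and S100A6 limits, and a correction for coding length and GC content by bin medians. GC content came from GENCODE v29 transcripts matched by symbol, for 92.7% of the measured rows. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

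The steps were tested on simulated data. For co-culture against monoculture, Poisson counts with 3-fold changes were recovered at 2-fold or more for 98.9% of 185 changed genes among 7136 tested, 3 of 6951 unchanged genes passed that size, and 95.8% of intervals held the true ratio. For HS5 against MM.1S, 189 of 189 changed genes among 6902 tested were recovered, and 3 of 6713 unchanged genes passed. A planted HS5 share of 5% came back as 5.03%, and the planted library totals came back with a difference of 0 reads. The planted share used unchanged monoculture profiles. In the real co-culture library FN1 was lower than in MM.1S alone, so the simulation does not show that the share estimate holds there.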

Results

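RNA was profiled in MM.1S, a human multiple myeloma cell line, grown alone or isolated after 24 h with HS5 bone marrow stromal cells, and in HS5 cells grown alone, with 1 library each. Library totals, recovered from the deposited RPKM values, came to 10343703, 11763251 and 5777398 reads. Ratios are scaled to these totals. The table used here carried 3118525, 3327448 and 938965 reads, with a median of 170, 172 and 51 reads per gene. The fewest reads stood behind the HS5 values. There were no replicates, and all intervals below cover counting error only.

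The comparison of co-cultured with monoculture MM.1S asks which transcripts differ in myeloma cells that have been next to stromal cells. Per the labels, only the co-cultured cells went through Accutase and CD138 beads. Co-culture and isolation therefore cannot be told apart in any ratio of that library to a monoculture. Higher or lower after co-culture means after both. The table used here left out transcripts low in any library, so transcripts silent in either MM.1S library could not be found. Ranked by the interval bound nearest to 0, the most raised transcript present was SGK1, a kinase induced by growth factors and steroid hormones (uc003qeo.4). It had 138 reads alone and 2433 after co-culture, 15.5-fold higher (log2 3.95, 95% interval 3.71 to 4.21). The transcription factor EGR1 was 12.9-fold higher (17 and 257 reads, log2 interval 3.03 to 4.53) and JUNB, an AP-1 subunit, 8.76-fold higher (2.79 to 3.51). Genes of DNA replication were lower, with a list median 2.60-fold down, and CDKN1A, the cyclin-dependent kinase inhibitor p21, was 5.07-fold lower (639 and 143 reads, log2 -2.34, interval -2.62 to -2.08). Of 7200 genes, 158 were at least 2-fold higher and 447 at least 2-fold lower. That split, 26.1% higher, rested on the scaling: the median of all genes was -0.19 (log2) with library totals, and TMM factors, under which it was 0.03, gave 277 higher and 219 lower, or 55.8% higher. Such a factor moves every ratio by the same amount, and several list medians are therefore also given against the median of all genes.

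Targets of STAT3 and interleukin-6 signalling were higher after co-culture. Their median over 14 measured genes was 1.34-fold up (log2 0.43, interval 0.29 to 1.86), 0.62 above the median of all genes and at the 100th percentile of matched random lists. JUNB, BCL3 (a nuclear regulator of NF-kB, 5.64-fold, log2 interval 2.13 to 2.90), the survival kinase PIM2 and SBNO2 (log2 1.26, 1.10 to 1.43) were at least 2-fold higher, and the interleukin-4 receptor gene IL4R was 2-fold lower (-1.01, -1.5 to -0.55). Between these, PIM1 was at 0.79 (0.37 to 1.23), STAT3 at 0.68 (0.47 to 0.89), BCL2L1 at 0.46 (0.29 to 0.63), MYC at 0.39 (0.32 to 0.46), MCL1 at 0.29 (0.17 to 0.41) and NFIL3 at -0.44 (-0.63 to -0.24). The genes of the JAK-STAT pathway itself had a median of -0.14 (16 genes, percentile 63.0), 0.05 above the median of all genes, and no member was 2-fold apart. TYK2 was at 0.48 (0.32 to 0.64), JAK1 at -0.40 (-0.57 to -0.23) and IL6ST, the shared receptor subunit gp130, at -0.31 (-0.42 to -0.21).

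Immediate early genes, which respond within minutes to outside signals, had a median 2.21-fold up (11 genes, log2 1.14, interval -0.16 to 3.26, 100th percentile). At least 2-fold higher were 7 of them, among them the phosphatase gene DUSP1 (9.58-fold, log2 interval 2.83 to 3.75), JUN (log2 2.46, 2.23 to 2.70) and ZFP36, which encodes an RNA-decay factor (5.22-fold, 2.19 to 2.60). ATF3 stood at -0.86 (-1.38 to -0.36). Heat shock genes lay the other way, 1.87-fold down at the median (9 genes, log2 -0.90, interval -1.39 to -0.40, percentile 0.04). All 9 were below the median of all genes, and HSPA8 (-1.71, -1.78 to -1.64), HSPH1 (-1.39, -1.58 to -1.21), DNAJA1 and CHORDC1 were at least 2-fold lower.

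Genes of S phase were the lowest of the fixed lists. Of 20 measured members 15 were at least 2-fold lower, the median was -1.38 (interval -1.49 to -1.07) and it lay at percentile 0. The uracil glycosylase UNG was 4.45-fold lower (295 and 75 reads), thymidylate synthase TYMS was at -1.81 (-2.14 to -1.49), the replicative helicase subunits MCM3 and MCM4 were at -1.45 and -1.43, and the sliding clamp PCNA was at -1.42. Of the other 5, RRM2 (-0.96, -1.09 to -0.83) and RRM1 (-0.79, -0.93 to -0.64) were lower by less, CDT1 (-0.21, -0.45 to 0.03) and CDC6 (-0.18, -0.40 to 0.03) had intervals that held 0, and cyclin E2, CCNE2, was at 1.82 (1.28 to 2.43), while CCNE1 was at -1.49 (-2.01 to -1.0). Genes of G2 and M phase had a median of -0.02 (20 genes, interval -0.26 to 0.16, percentile 91.8), which was 0.19 under TMM, and none was 2-fold apart. A correction for coding length and GC content, chosen after the results were seen, took this median from 0.17 to 0.28 above that of all genes, outside the central 95% of random lists (percentile 99.2, upper bound 0.22). MKI67 was at -0.48 (-0.55 to -0.41) and UBE2C at 0.70 (0.35 to 1.06). Replication-dependent histone genes had a median of -0.11 (12 genes, percentile 66.8), or 0.10 under TMM. The libraries were made from poly(A) RNA, so histone values may depend on that selection and need not follow histone expression.

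Plasma cell identity genes had a median of 0.42 (13 genes, interval -0.51 to 1.86, percentile 99.9) and went both ways. The transcription factor KLF2 (2.43, 1.84 to 3.13), PIM2, the B cell coactivator POU2AF1, XBP1 (1.02, 0.91 to 1.13) and MZB1 (1.02, 0.96 to 1.08) were at least 2-fold higher. The J chain gene IGJ was at -0.93 (-0.96 to -0.89), SDC1, which encodes the CD138 used for isolation, at -0.54 (-0.64 to -0.44), and IRF4 at -0.46 (-0.55 to -0.37). Without PIM2, the member shared with the STAT3 list, the median was 0.27 and at percentile 97.1, inside the central 95% of random lists; this comparison was added after the values were seen.

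Class I antigen presentation genes had a median of 1.24 (5 genes, interval -0.003 to 1.66, 100th percentile), with NLRC5, an activator of class I genes (1.53, 1.18 to 1.89), and HLA-B among those at least 2-fold higher and B2M at 0.92 (0.85 to 0.99). Cholesterol synthesis genes had a median of 0.41 (18 genes, interval -0.02 to 0.87, 100th percentile), with squalene epoxidase SQLE the highest (1.14, 0.80 to 1.5). Ribosomal protein genes were at 0.38 (35 genes, interval 0.32 to 0.43, 100th percentile): 35 of 35 lay above the median of all genes and none was 2-fold apart.

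The other lists with 3 or more measured genes lay inside the central 95% of random lists, before and after the length and GC correction. Interferon-stimulated genes were at 0.07 (10 genes, percentile 92.5), with IRF9 at 1.47 (0.86 to 2.15), OAS1 at 1.12 (0.63 to 1.65) and IFIT5 at -2.38 (-3.21 to -1.69). NF-kB targets were at -0.01 (12 genes, percentile 87.6), with the adhesion molecule ICAM1 at 1.6 (1.14 to 2.11) and the NF-kB inhibitor TNFAIP3 4.75-fold lower. Chaperone and XBP1 genes of the endoplasmic reticulum were at -0.02 (20 genes, percentile 74.95), with DNAJB9 at 1.09, EDEM1 at 1.08 and SEL1L at -0.95. Genes of the ATF4 amino acid response were at -0.27 (19 genes, percentile 25.2), hypoxia and glycolysis genes at -0.15 (16 genes, percentile 53.4), adhesion and homing genes at -0.39 (9 genes, percentile 12.3) with ITGA4, the alpha-4 integrin, at -1.93 (-2.11 to -1.75), BCL2 family genes at -0.44 (7 genes, percentile 13.3) with BAX at -1.02, and MAF-driven myeloma genes at -0.17 (3 genes, percentile 39.2) with MAF itself at 1.08 (1.01 to 1.15). With TMM factors the JAK-STAT (0.07), NF-kB (0.20), endoplasmic reticulum (0.19), hypoxia (0.07) and MAF (0.04) medians lay above 0. The myeloid and T cell, mitochondrial and immunoglobulin lists had 0 genes in the table used here, the class II list had 1, CD74 at 0.04 (-0.05 to 0.14), and the stromal cytokine list had 2 measured genes, TGFB1 at -1.41 (-1.72 to -1.12) and VEGFA at 0.09 (-0.28 to 0.46).

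**Figure D1:**
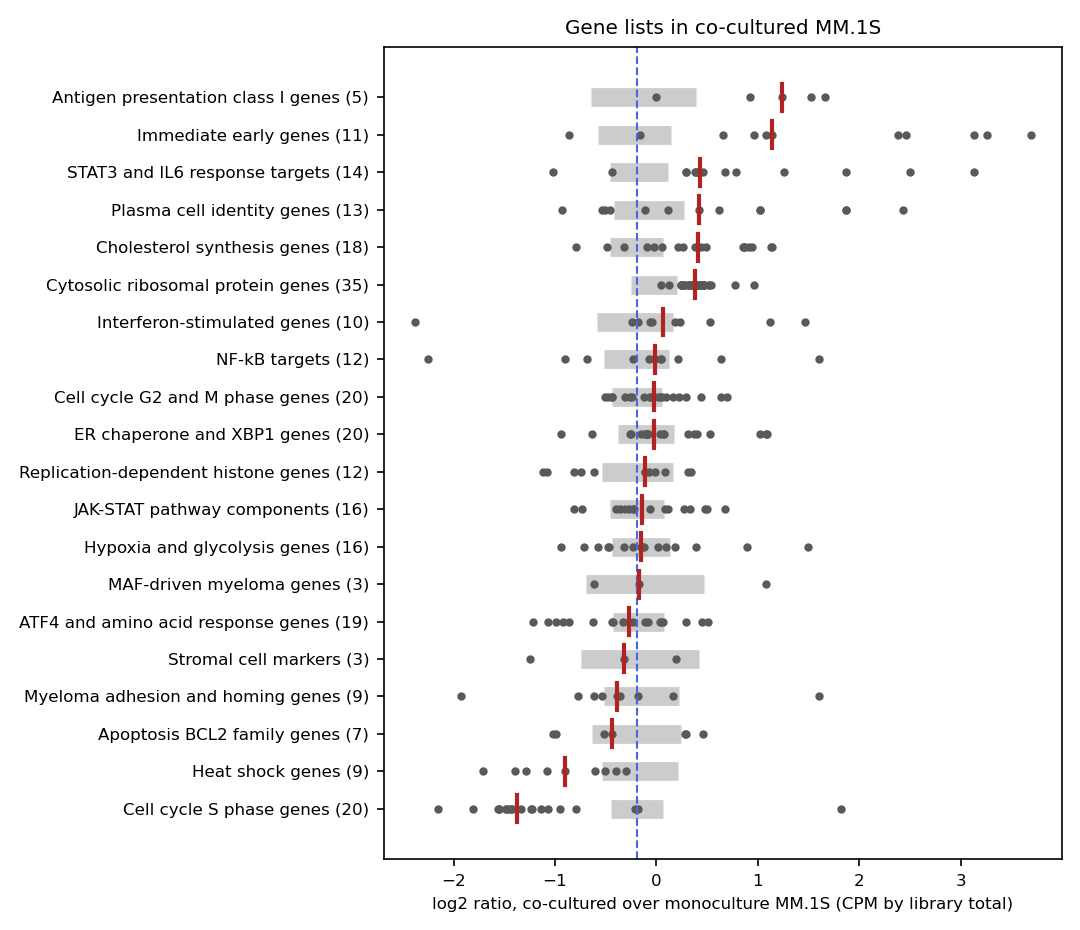
Each grey point is a gene of a list fixed before the data were examined, placed by its log2 ratio of co-cultured to monoculture MM.1S (x axis, CPM by library total), with lists on the y axis and their number of measured genes in parentheses. Red bars are list medians, pale bars the central 95% of medians of 10000 matched random lists, and the dashed line the median of all genes (-0.19), with the S phase median at -1.38 and the class I median at 1.24.

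Comparing the co-culture library with both monocultures sets apart transcripts whose level a mixture of the unchanged cell lines could not reach. Among 6927 genes with 50 or more reads in the co-culture library, 106 were at least 2-fold above both monocultures. TP53INP1, a stress-induced p53 partner, was furthest above (247 reads in MM.1S, 2347 after co-culture and 23 in HS5, 8.34-fold over MM.1S, log2 interval 2.87 to 3.26), followed by the kinase SIK1 (6.84-fold, 2.46 to 3.12), ZFP36 and GADD45A, a growth arrest gene (6.46-fold, 2.40 to 3.01). The mitochondrial isocitrate dehydrogenase IDH2 went from 2140 to 9281 reads (3.81-fold, 1.86 to 2.00), PIM2 from 3472 to 14382 (3.64-fold, 1.81 to 1.92) and POU2AF1 from 1248 to 5168 (3.64-fold, 1.77 to 1.95), against 33, 21 and 6 reads in HS5. DFNB31 was 4.04-fold, HBEGF, an EGF receptor ligand, 5.0-fold, NLRP1 3.51-fold, EML2 3.31-fold, SIDT2 2.86-fold, HDAC6 2.84-fold and OTUD5 2.74-fold above MM.1S alone.

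Among 3896 genes with 50 or more reads in both monocultures, 115 were at least 2-fold below both. The counts above and below both were 129 and 90 with TMM factors, and 167 and 70 with ratios centred on the median of all genes, a setting chosen after seeing the data. Of the genes lowest against MM.1S alone, the scaffold gene HOMER3 was 5.64-fold lower (776 and 156 reads, log2 -2.50, interval -2.76 to -2.25), the cell cycle repressor E2F7 5.33-fold (-2.85 to -2.02), the cadherin FAT1 4.26-fold (-2.21 to -1.97) and the microfibril gene FBN2 4.58-fold (-2.51 to -1.90). C1orf96 (6.71-fold, 91 and 15 reads), FAM105A (5.52-fold), ARHGEF3 (5.09-fold), FRMD6 (5.04-fold), RNF219 (4.89-fold), TEX9 (4.66-fold), C21orf91 (4.64-fold) and DPYSL2 (4.26-fold) completed the set with CDKN1A, TNFAIP3 and UNG.

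**Figure D2:**
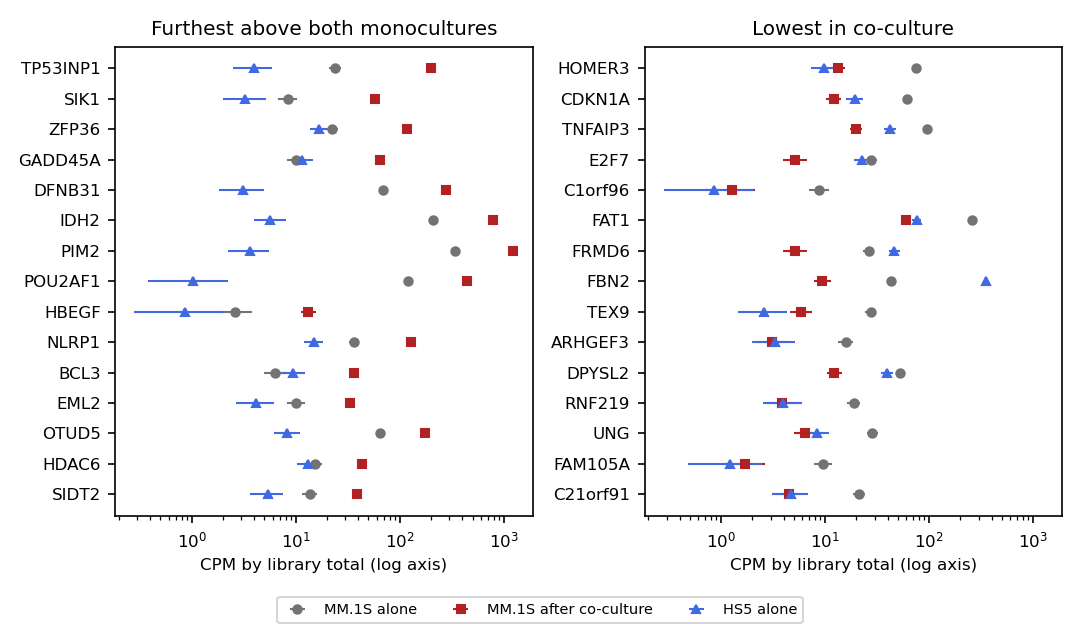
CPM by library total (x axis, log scale) for the 15 genes furthest above both monocultures (left) and the 15 lowest in co-culture (right), in MM.1S alone (grey circles), MM.1S after co-culture (red squares) and HS5 alone (blue triangles), with 1 library each. Bars are exact 95% Poisson intervals of the counts; PIM2 had 3472, 14382 and 21 reads in the 3 libraries.

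Stromal transcripts in the isolated MM.1S cells were low. FN1, the fibronectin gene and the most abundant of them, stood in the co-culture library at 0.394% of its HS5 level (interval 0.352 to 0.438) and in MM.1S alone at 0.933%, so the HS5 share it gave was -0.544% (-0.628 to -0.463) and was taken as 0. MME stood at 1.04% (0.790 to 1.35) and S100A6, a calcium-binding protein gene, at 1.19% (0.824 to 1.68), with 34 reads after co-culture against 5 in MM.1S alone. These levels bound the HS5 RNA in that library, if HS5 cells kept these transcripts in co-culture. The stromal marker list, with 3 of its 31 genes in the table, had a median of -0.32 (percentile 33.2), with FN1 at -1.24 (-1.44 to -1.05), SPARC at -0.32 (-0.70 to 0.06) and CAV1 at 0.20 (-0.11 to 0.51). EGR1, 12.9-fold higher after co-culture, was higher still in HS5, with a log2 ratio of co-culture to HS5 of -2.03. IL32, 11.8-fold higher, was at -0.34, from only 140 reads after co-culture and 87 in HS5. SGK1, with 940 reads in HS5, was at 0.35, less than the shift between scalings. No intervals are given for these ratios to HS5.

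HS5 and MM.1S grown alone were compared to show how the 2 cell lines differ. Only transcripts above 1 RPKM in all 3 libraries were in the table used here. Genes low or absent in either line thus entered neither the rankings nor the list medians. S100A6 was 455-fold higher in HS5 (log2 8.83, interval 7.74 to 10.59), the neprilysin gene MME 115-fold, FN1 107-fold (41685 and 696 reads), the small GTPase gene RND3 75.5-fold, the protease inhibitor SERPINE2 64.7-fold, IGFBP6 55.7-fold, EGR1 52.9-fold, WNT5A 49.0-fold, and DCBLD2 and ASS1 37.2-fold each. The genes furthest higher in MM.1S were LAPTM5 593-fold (5841 and 5 reads, log2 -9.21, interval -10.97 to -8.13), IGJ 363-fold, the beta-7 integrin ITGB7 306-fold (56064 and 102 reads), MZB1 244-fold, CD74 152-fold, IRF4 124-fold, SYNGR2 106-fold, MAF 101-fold, SLC1A4 101-fold and PIM2 90.2-fold. Of 7081 genes, 439 were at least 2-fold higher and 3585 at least 2-fold lower in HS5, 10.9% higher, with a median of all genes of -1.02. The HS5 library had a smaller share of its reads in the table, and TMM factors, with a median of all genes of -0.11, gave 1189 higher and 1516 lower, or 44.0% higher.

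The lists parted the cell lines as follows. List medians are measured from the median of all genes. Single genes are given as log2 ratios not measured from it. Plasma cell identity genes lay at -4.33 (12 genes, all at least 2-fold lower in HS5, percentile 0), with PRDM1 at -5.67 (-6.46 to -5.04), and MAF-driven genes at -5.65 (3 genes). ATF4 response genes were at -1.91 (19 genes), cholesterol synthesis genes at -1.32 (18 genes), endoplasmic reticulum genes at -1.05 (20 genes) and ribosomal protein genes at -1.0 (34 genes), each at percentile 0. Stromal markers lay at 3.51 (3 genes, percentile 99.96) and stromal cytokines at 2.92 (3 genes, percentile 99.8), with FGF2 at 4.30 (3.74 to 4.98). Histone genes were at 2.62 (15 genes), immediate early genes at 2.22 (11 genes), interferon-stimulated genes at 1.93 (12 genes, ISG15 at 4.13 and BST2 at -4.12) and G2 and M phase genes at 1.18 (20 genes), each at the 100th percentile, and hypoxia and glycolysis genes at 0.94 (17 genes, percentile 99.8). The histone value may reflect the poly(A) selection of each library and not the cell lines, which was not tested. The log2 median of the interferon list itself, not measured from that of all genes, was 0.92, and -2.03 among genes with 200 or more reads. JAK-STAT genes (0.56), STAT3 targets (0.57), heat shock (0.26), class I (0.23), NF-kB (-0.09), adhesion (-0.15), S phase (-0.24) and BCL2 family genes (-0.51) lay inside the central 95% of random lists.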

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

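The table-sum, centring, MM.1S-only TMM, length and GC, and FN1 or S100A6 settings were chosen only after the results were seen. No paired analysis was possible because each group had 1 library. Of 486 values under alternatives, 409 stayed within 1.5 times the count or within the interval of the list's median or HS5 share, 73 moved further, and 4 turned the sign of a list outside the central 95% of random lists. Of all list medians under alternatives, 39 had another sign than reported: 4 in such lists, given below, and 35 in lists inside that range, such as STAT3 targets in HS5 (0.46 with TMM) and BCL2 family genes in co-culture (0.29 at a minimum of 200 reads). The 25th and 75th percentile shares, the pooled share and the minimum of 500 reads for markers gave identical values by construction, since FN1 alone was a marker and the subtraction took off 0. For the same reason the counts higher and lower in co-culture after subtraction equalled those without it under every setting run for both, and these are given once below. The whole-interval setting was not run after subtraction, and counts above and below both monocultures were taken without it.

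With TMM, 277 genes were higher and 219 lower in co-culture, with median-of-ratios 268 and 228, with TMM over the MM.1S libraries 257 and 241, and with centring 257 and 241. HS5 against MM.1S gave 1189 and 1516 with TMM, 1225 and 1464 with median-of-ratios, 1174 and 1535 with table sums, and 1347 and 1325 with centring. Centring also gave 167 genes above and 70 below both monocultures. A minimum of 200 reads gave 83 and 199 in co-culture, 68 above and 25 below both, and 176 and 2160 for HS5, from fewer genes. With the whole interval beyond 2-fold the counts were 56 and 133, 32 above and 34 below both, by construction. The HS5 share was -0.255% with TMM, -0.252% with median-of-ratios, 0.186% from all HS5-dominated genes, and 0.394% or 1.19% with FN1 or S100A6 taken wholly as HS5 RNA; the cause of these shifts was not tested.

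In co-culture, TMM, centring and the length and GC correction, which also centres, put the G2 and M list at 0.19, 0.17 and 0.28 and the ribosomal list at 0.59, 0.57 and 0.49, table sums put the ribosomal list at 0.47, and TMM put the histone list at 0.10. In HS5 against MM.1S, the median of all genes moved by about 0.9 to 1.0 and carried the lists with it. In the order TMM, table sums and centring, JAK-STAT genes were at 0.45, 0.44 and 0.56, S phase at -0.35, -0.37 and -0.24, G2 and M at 1.07, 1.06 and 1.18, cholesterol at -1.43, -1.45 and -1.32, endoplasmic reticulum at -1.16, -1.18 and -1.05, histones at 2.5, 2.49 and 2.62 and ribosomal proteins at -1.12, -1.13 and -1.0. Hypoxia genes changed sign, to 0.83, 0.82 and 0.94, and centring put ATF4 genes at -1.91. Interferon-stimulated genes changed sign to -2.03 at a minimum of 200 reads, where fewer members remained. Depth was lowest for HS5, with a median of 51 reads per gene.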

Other observations

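All lists and tests in this part were chosen only after the main results had been seen, and the outcomes of the length and GC tests and of the added lists' unseen members were not known when these were chosen.

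Of 7 added lists, 4 had a median of unseen members outside the central 95% of matched random lists. Above and below the median of all genes were 2 and 28 DNA repair and replication genes and 6 and 25 proteasome genes. For translation factors these counts were 21 and 1, and for the respiratory chain 28 and 6. Most members thus lay on 1 side but not all, and FANCD2, PSMD8, NPM1 and NDUFS3 lay on the other side beyond counting error. Genes of DNA repair and chromatin replication were at -0.81 (30 genes, interval -1.07 to -0.52, percentile 0), with POLA1 at -1.65, RFC3 at -1.33 and FANCD2 at 0.30. This list includes replication genes such as POLA1 and RFC3, so it is not independent of the S phase result. Proteasome subunit genes were at -0.46 (31 genes, -0.65 to -0.28, percentile 0.25), with PSMD1 at -1.12 and PSMC2 at -1.02. Translation factor genes whose mRNAs carry a 5-prime oligopyrimidine tract, as those of ribosomal proteins do, were at 0.26 (22 genes, 0.21 to 0.47, percentile 99.2), with EEF2 at 0.59. Respiratory chain genes were at 0.0315 (34 genes, -0.09 to 0.25, percentile 99.4). Their interval held 0, and they stood out only against the median of all genes, -0.19. After the length and GC correction, which also centres, DNA repair and replication genes were at -0.62 (percentile 0) and proteasome genes at -0.19 (percentile 1.475). Translation factors were then at 0.46 (percentile 99.96) and respiratory chain genes at 0.20 (percentile 99.5). MYC-related ribosome biogenesis genes were at -0.15 (26 genes, -0.32 to 0.003, percentile 54.3), inside the range set in advance as evidence against a joint change. That bound was wrong, since members went both ways, from RRP12 at 0.44 (0.31 to 0.58) to TFB2M at -0.73 (-1.10 to -0.37). A median inside the range then decides nothing, so the question stays open. Unseen p53 targets were at -0.33 (17 genes, percentile 14.1, or 0.68 after the length and GC correction), among them MDM2 at -1.72, and the tests of this list and of FOXO targets at 0.0108 (17 genes, percentile 91.2) leave the question open, because members already seen were left out.

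Immediate early genes were higher after co-culture. The values argue against HS5 RNA, if HS5 cells in co-culture kept the levels they had alone. The 2-fold higher members would need a median HS5 share of 159%, the lowest being 14.8% for IER2, against at most 1.68% from S100A6. Since members were picked as 2-fold higher, none could have needed less than that bound, so this is arithmetic and not a test. A rise of these genes in HS5 cells during co-culture was not examined. The labels give cell isolation with Accutase and CD138 beads for the co-culture library alone, so its part was left open. The heat shock genes, at -0.90, did not go up, which decides nothing because no monoculture was isolated for comparison. A response to stromal signals may also account for the rise and was not tested.

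S phase genes were lower after co-culture. The median member would need a dilution of 61.5% by RNA that holds none of these transcripts, far above the 1.68% bound. HS5 RNA did hold them. The list median was 0.418 of the MM.1S level in HS5 alone and 0.385 in the co-culture library. No share of HS5 RNA at those levels would lower the list median that far. Measured from the median of all genes, the list was at -1.19 before and -1.16 after the correction for coding length and GC content (percentile 0). A lower share of cycling cells alone would lower the G2 and M list too, which was at -0.0234. Lower expression of replication genes after 24 h of co-culture may be biological, a hypothesis drawn from these same libraries and not tested. Isolation with Accutase and CD138 beads was given for the co-culture library alone, so its part stays open. Differences in culture density or feeding were not recorded in the labels.

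Ribosomal protein genes were higher after co-culture. Measured from the median of all genes, the list went from 0.57 to 0.49 with the length and GC correction and stayed at the 100th percentile. Without correction or centring, lists of equally abundant genes reached 0.21 at their upper bound, below the 0.38 observed. No biological explanation was tested. Neither was cell isolation, given for the co-culture library alone, nor library preparation, which was done once per group.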
